A study of Homo sapiens with 4 samples.

How the data were processed

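Gene expression was measured by RNA sequencing in MDA-MB-231, an established human cell line derived from a triple-negative breast cancer. Per the labels' protocols, cells were grown in DMEM with fetal bovine serum and were treated for 24 h with vehicle or with MGH-CP1 at 10 µM. The series title names this compound as an inhibitor of TEAD palmitoylation. TEAD proteins are the DNA-binding partners of YAP and TAZ, the transcriptional effectors of the Hippo pathway. RNA was extracted on silica columns, poly(A) RNA was captured on oligo-dT beads, and cDNA was made from fragmented RNA with random hexamers, per the labels' protocols. Sample titles placed 2 libraries in the vehicle group and 2 in the MGH-CP1 group. Nothing in the labels states that the replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

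The authors deposited 1 table of FPKM values (fragments per kilobase of gene length, scaled to the reads of the library) for 48162 genes, with gene identifier, symbol, chromosome, strand, start, end, length and gene type. Per the submitters' processing notes, base calls were converted with CASAVA 1.8 and reads were aligned with STAR to hg19. The STAR version, the read counter, the use of strand in counting and the annotation release are not given in the sources used here. All 4 value columns of the table belong to the 4 labelled samples. In the symbol column, 29 entries read as calendar dates, as spreadsheet programs write some symbols, so genes were joined by identifier. The reference at hand was GRCh38 with GENCODE 29, another build than hg19, so all coordinates are those of the authors' table on hg19, and GENCODE 29 transcripts served only to give GC content by gene identifier (11544 of 11790 tested genes, 97.9%).

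The depth was recovered from the FPKM values. Multiplied by gene length, the values above 0 of each library were whole multiples of 1 step (100% of them within 0.001 of a whole number), and the step was inversely proportional to the sum of these multiples. Each multiple was therefore taken as a number of reads. The totals over all listed genes were 18485701 and 16790645 reads for the vehicle libraries and 17295817 and 16960448 reads for the MGH-CP1 libraries. A single read on a gene of 1 kb was worth 0.0541 to 0.0596 FPKM, so short genes near 1 FPKM rested on few reads. Values within a group differed by more than sampling noise: the median chi-square per gene between replicate libraries, over genes with at least 100 reads in the pair, was 1.78 in vehicle and 1.05 in MGH-CP1, where sampling alone gives 0.455. No library was a copy of another, and each was counted as 1 replicate.

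MGH-CP1 was compared with vehicle with limma 3.58.1 in R 4.3.3. The FPKM values as scaled by the authors were transformed to log2(FPKM + 1), genes with a mean of at least 1 FPKM over the 4 libraries were kept (11790 genes), a model with group as its only term was fitted, and variances were moderated with a mean-variance trend. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. Log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values, so mean FPKM values are given for the genes named by the rule below. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

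Before the data were examined, 40 gene lists were fixed with 1002 entries, of which 996 were matched to the table. They covered YAP and TEAD targets, Hippo pathway components, proliferation, metabolism, stress responses, signalling, cell identity, markers of fibroblasts, immune and endothelial cells, and RNAs that report on poly(A) selection. Lists with at least 3 tested members (38 lists) were tested with camera in limma with a preset inter-gene correlation of 0.01, two-sided, and adjusted over the 38 lists. Each was tested again with camera and an estimated correlation. In that form camera takes its degrees of freedom from the residuals, of which this fit had 2, so few lists could pass after adjustment. Each was also tested with fry, which asks whether the members move on balance in a common direction or, in its mixed form, in either direction. The list of PI3K and AKT genes, which holds SOX4, and the entry VGLL3 were chosen with knowledge of published work on the compound that may rest on these libraries, so they are not independent evidence.

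The rule for named genes was also fixed before the data were examined. It named 13 genes in every case (CYR61, CTGF, ANKRD1, AMOTL2, AXL, YAP1, WWTR1, TEAD1, TEAD2, TEAD3, TEAD4, VGLL3 and SOX4). To these it added the 6 largest rises and the 6 largest falls among called genes that the table types as protein-coding and whose MGH-CP1 values lay on the same side of both vehicle values. It further added the 3 largest changes among called members of the 10 lists with the smallest p, and the 3 largest changes in the YAP and TEAD target, Hippo and PI3K lists. The rule gave 48 genes, of which 1 is not reported here. Genes named outside it are said to have been chosen after their values were seen.

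The scripts were tested on simulated data drawn from the real means and depths, in 10 sets with 200 changed genes each among 11762 to 11809 genes. All genes were given the same dispersion, 0.000993, taken from the vehicle pair. The real data had far more called genes, and a spread that may differ among genes, so the shares of false calls need not hold there. For this comparison the limma fit recovered 42.8% of the 1.25-fold, 76.2% of the 1.5-fold, 97.8% of the 2-fold and 93.4% of the 4-fold changes, and 9.35% of its calls were false. On the same sets, voom in limma on the recovered reads recovered 63.8%, 84.2%, 97.6% and 93.6%, with 4.34% of calls false. The list test made 1 false call over the 10 sets of 38 lists. Simulated genes varied independently of each other, so this count does not measure the error of the test for lists whose members vary together.

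Of the 16 alternatives, 13 were planned and covered the pseudocount, the filter on low values, scaling, the variance trend, the replicate number as a block, leaving out each library and protein-coding genes alone. The other 3 were added after seeing the data: voom on recovered reads, scaling to reads on nuclear genes, and a correction for GC content and gene length per library. Another 7 gene lists were written after the gene results had been seen, leaving out the genes whose values prompted them.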

Results

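Expression profiles were obtained from 4 poly(A)-selected RNA libraries of MDA-MB-231 breast cancer cells, 2 treated with vehicle and 2 treated with 10 µM MGH-CP1 for 24 h. The series describes MGH-CP1 as an inhibitor of TEAD palmitoylation, and the comparison asked which transcripts changed when cells were exposed to it. Libraries held 16790645 to 18485701 reads over the listed genes, and 20000 to 20544 genes had at least 1 read in a library. The 10 genes with the most reads took 4.51% to 4.74% of each library. Across the 11790 genes tested, the Pearson correlation of log2(FPKM + 1) values was 0.992 between the vehicle libraries, 0.995 between the MGH-CP1 libraries and 0.964 between groups for the closest pair. These correlations are across genes, which are not independent replicates. Expression is given as mean FPKM ± SD (n = 2 libraries per group), and fold changes as log2 values of MGH-CP1 over vehicle ± SE.

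Canonical YAP and TEAD target genes, genes of DNA replication and mitosis, and genes of ribosome biogenesis were lower with MGH-CP1 than with vehicle. CYR61, a secreted matricellular protein and a standard TEAD target, fell 3.90-fold, from 232 ± 5.08 to 59.5 ± 4.37 FPKM. All 37 tested genes of the S phase list fell, with a median log2 fold change of -1.73. Most mRNAs encoded by the mitochondrial genome rose (11 of 13), as did 21 of 33 hypoxia and glycolysis genes. As lists, these groups passed camera with a preset correlation but not with an estimated one (lowest adjusted p = 0.308). The estimated form rests on few residual degrees of freedom, so few lists could pass it.

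With limma, 2355 genes were higher and 2956 lower at an adjusted p under 0.05, out of 11790 tested. The change was at least 2-fold on the log2(FPKM + 1) scale for 117 of the higher and 276 of the lower genes. These counts depend on the scale, being 246 and 435 with a pseudocount of 0.1 and 260 and 446 with voom. The number of higher genes was 1524 without MGH-CP1 replicate 1, 1460 without MGH-CP1 replicate 2, and 1568 with no filter on low values. In simulated data of the same depth, with 200 changed genes and the same dispersion for all, 9.35% of limma calls and 4.34% of voom calls were false. These shares need not hold for the real calls, which were far more numerous. On the recovered reads voom called 2607 higher and 3153 lower genes. These included 5147 of the 5311 genes called by the limma fit, in the same direction.

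**Figure D1:**
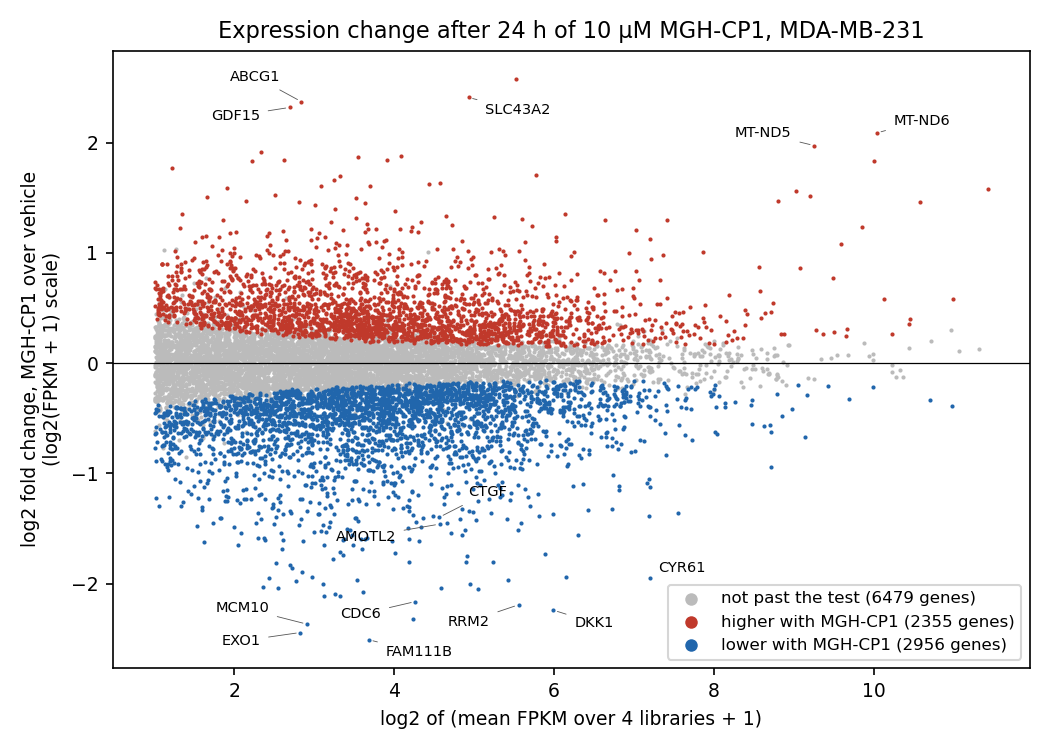
Log2 fold change of MGH-CP1 over vehicle for each of the 11790 tested genes (vertical axis, log2(FPKM + 1) scale) against log2 of the mean FPKM over the 4 libraries plus 1 (horizontal axis). Red points mark the 2355 higher and blue points the 2956 lower genes, grey points did not pass the limma test, and the labelled genes are 5 of the 6 largest rises and the 6 largest falls among genes typed as protein-coding in the authors' table, and the 3 TEAD targets with the largest changes.

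TEAD target genes fell as a group. Of the 22 tested members of the YAP and TEAD target list, 17 fell and the other 5 did not pass the gene test, and the count was also 17 adjusted over the list alone. The median log2 fold change of the list was -0.63 (camera, adjusted p = 4.66e-08; adjusted p = 0.308 with an estimated correlation). CYR61 (ENSG00000142871, hg19 chromosome 1, 86046444 to 86049645, plus strand) had a log2 fold change of -1.95 ± 0.07 (limma, adjusted p = 8.64e-06). CTGF (ENSG00000118523, chromosome 6, 132269316 to 132272513, minus strand), a matricellular protein related to CYR61, went from 33.3 ± 1.37 to 12.1 ± 1.37 FPKM, a log2 fold change of -1.40 ± 0.08 (limma, adjusted p = 4.34e-05). ANKRD1 (ENSG00000148677, chromosome 10, 92671853 to 92681033, minus strand), which encodes an ankyrin repeat protein, went from 90.4 ± 7.12 to 34.4 ± 0.441 FPKM (log2 fold change -1.37 ± 0.07). AMOTL2 (ENSG00000114019, chromosome 3, 134074716 to 134094321, minus strand), a target that also encodes a YAP-binding angiomotin protein, went from 33.8 ± 2.10 to 11.6 ± 0.0881 FPKM (log2 fold change -1.46 ± 0.07). The receptor tyrosine kinase gene AXL (ENSG00000167601, chromosome 19, 41725108 to 41767671, plus strand) fell from 553 ± 9.03 to 288 ± 13 FPKM, and an annotated antisense gene overlapping it averaged 3.17 FPKM. A broader conserved YAP signature behaved alike, with 33 of 50 tested members lower and 5 higher (34 lower and 5 higher adjusted over the list alone) and a median of -0.40 (camera, adjusted p = 3.88e-06; adjusted p = 0.308 with an estimated correlation). It shares 7 tested members with the cell cycle lists and also holds 9 of the TEAD targets above, among them CYR61, CTGF and AMOTL2.

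The genes of YAP, TAZ and the TEAD proteins did not change in a common direction. YAP1 stood at 54.3 ± 1.92 FPKM in vehicle and 57.7 ± 1.63 with MGH-CP1, a log2 difference of 0.09 that did not pass (limma, adjusted p = 0.261), with a 95% interval of -0.05 to 0.22. WWTR1, which encodes TAZ, rose from 20.5 ± 0.213 to 29.8 ± 0.848 FPKM (log2 fold change 0.52 ± 0.06; limma, adjusted p = 0.000503). TEAD4 (ENSG00000197905, chromosome 12, 3068496 to 3149839, plus strand) fell from 12.6 ± 0.712 to 6.37 ± 0.474 FPKM (log2 fold change -0.88 ± 0.08; limma, adjusted p = 0.000225). TEAD1, at 40.1 ± 5.02 and 37.8 ± 2.05 FPKM, and TEAD3, at 24.0 ± 0.258 and 23.2 ± 0.356 FPKM, did not pass (limma, adjusted p = 0.504 and 0.577). TEAD1 was called lower only without vehicle replicate 1 (log2 fold change -0.20; limma, adjusted p = 0.029, with a highest adjusted p of 0.893 over the alternatives). TEAD2 rose from 6.51 ± 0.478 to 7.97 ± 0.313 FPKM by a narrow margin (limma, adjusted p = 0.0429). That call was lost in 5 of the 16 alternatives, among them no filter, without vehicle replicate 2 and without either MGH-CP1 library (limma, highest adjusted p = 0.216, without MGH-CP1 replicate 2). VGLL3, a TEAD cofactor gene, averaged 0.633 ± 0.101 and 0.622 ± 0.142 FPKM and lay below the limit for testing. Among 24 tested Hippo pathway genes 3 rose and 11 fell (4 and 13 adjusted over the list alone), including WWC1, which encodes the scaffold protein KIBRA and went from 34.1 ± 1.16 to 17.2 ± 0.672 FPKM. The list, which shares AMOTL2, LATS2 and PTPN14 with the TEAD targets above, did not pass (camera, adjusted p = 0.145). In the list of palmitoylation enzymes 4 of 27 members rose and 5 fell (2 and 4 adjusted over the list alone), and the list did not pass (camera, adjusted p = 0.975).

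**Figure D2:**
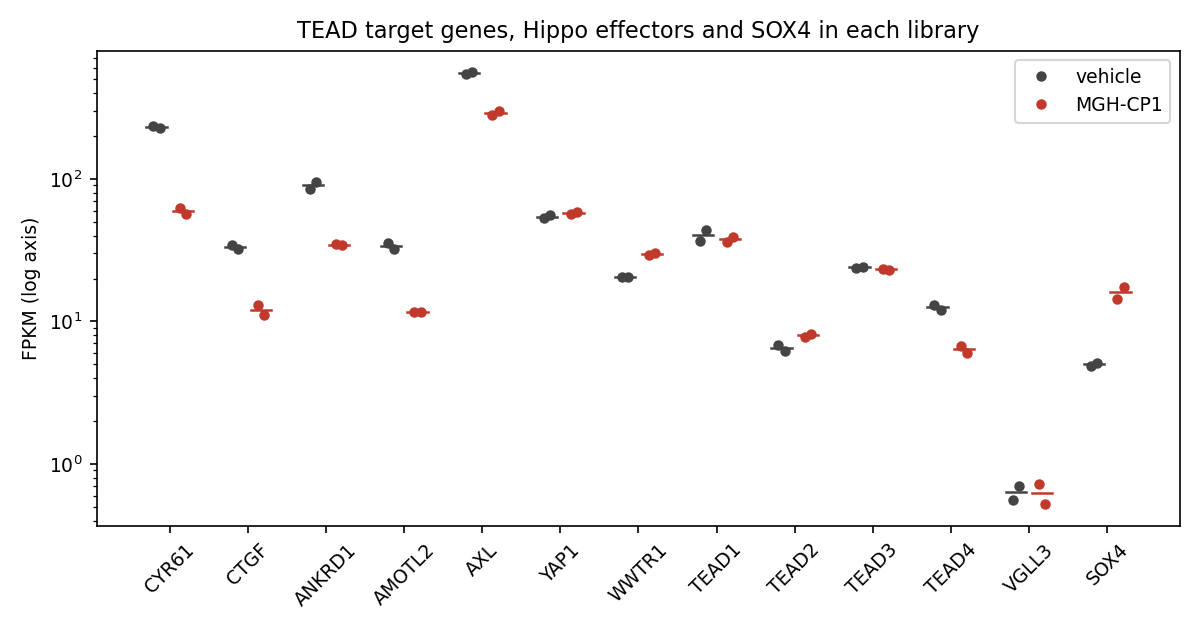
FPKM (log axis) of 13 genes in each of the 4 libraries, vehicle in dark grey and MGH-CP1 in red, with a bar at each group's mean. The 5 target genes from CYR61 to AXL were lower in both MGH-CP1 libraries than in both vehicle libraries, and SOX4 was higher in both.

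Genes of DNA replication showed the largest coordinated fall. All 37 tested members of the S phase list fell, and the same number adjusted over the list alone (camera, adjusted p = 1.3e-23; adjusted p = 0.308 with an estimated correlation). UHRF1, a reader of hemimethylated DNA, went from 30.3 ± 2.15 to 5.26 ± 0.148 FPKM (log2 fold change -2.32 ± 0.08). RRM2, the regulated subunit of ribonucleotide reductase, went from 76.2 ± 0.629 to 15.9 ± 0.704 FPKM (log2 fold change -2.19 ± 0.06), and CDC6, which helps load the replicative helicase, from 30.4 ± 2.11 to 6.03 ± 0.844 FPKM (log2 fold change -2.16 ± 0.10). All 41 tested genes of the G2 and mitosis list also fell, as they did adjusted over the list alone, by a smaller median of -0.84 (camera, adjusted p = 4.18e-19; adjusted p = 0.308 with an estimated correlation). They included the proliferation marker MKI67, from 80.5 ± 6.70 to 30.3 ± 2.53 FPKM, the mitotic kinase gene CDK1, from 52.2 ± 4.23 to 19.7 ± 1.44 FPKM, and the kinesin gene KIF23, from 23.7 ± 1.75 to 8.90 ± 0.0545 FPKM. Of the 6 largest falls among genes typed as protein-coding in the authors' table, where UHRF1 is typed as a processed transcript, 5 act in or around DNA replication and repair: FAM111B, EXO1, MCM10, RRM2 and CDC6. FAM111B went from 20.9 ± 1.24 to 2.84 ± 0.0511 FPKM, the exonuclease gene EXO1 from 11 ± 0.226 to 1.2 ± 0.0428 FPKM, and MCM10 from 11.6 ± 0.218 to 1.44 ± 0.164 FPKM. The remaining gene was DKK1 (ENSG00000107984, chromosome 10, 54074056 to 54077802, plus strand), a secreted Wnt antagonist, which fell 4.90-fold from 104 ± 5.04 to 21.3 ± 1.46 FPKM (log2 fold change -2.24 ± 0.07; limma, adjusted p = 7.67e-06).

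Ribosome biogenesis genes fell too. In this list of nucleolar and MYC-responsive genes 24 of 25 tested members were lower, and 25 adjusted over the list alone, with a median of -0.77 (camera, adjusted p = 1.69e-11; adjusted p = 0.357 with an estimated correlation). NOLC1, a nucleolar chaperone gene, went from 63.1 ± 0.716 to 28.8 ± 0.715 FPKM and DKC1, which encodes the pseudouridine synthase dyskerin, from 39.4 ± 1.07 to 18.2 ± 0.950 FPKM. NOP16 went from 12.7 ± 1.18 to 4.30 ± 0.171 FPKM and overlaps HIGD2A on the opposite strand, which averaged 20 FPKM, so its value is uncertain. Of the 40 ribosomal protein genes 7 fell (5 adjusted over the list alone), and this list did not pass (camera, adjusted p = 0.186).

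Transcripts of the mitochondrial genome rose as a group. Their share of all reads was 0.676% and 0.645% in the vehicle libraries and 1.81% and 1.54% in the MGH-CP1 libraries. Of the 13 mRNAs 11 rose and 1 fell (12 and 1 adjusted over the list alone), with a median log2 fold change of 1.48 (camera, adjusted p = 8.14e-08; adjusted p = 0.37 with an estimated correlation). MT-ND6, the complex I subunit encoded on the opposite strand from the others, went from 401 ± 22.5 to 1709 ± 33.0 FPKM (log2 fold change 2.09 ± 0.07). MT-ND5 went from 247 ± 8.58 to 974 ± 14.8 FPKM and MT-ND4, which overlaps MT-ND4L, from 447 ± 10.2 to 1609 ± 219 FPKM. The exceptions, named after their values were seen, were MT-ND3, which fell from 2298 ± 204 to 1763 ± 251 FPKM (limma, adjusted p = 0.0345), and MT-ATP8, at 14.4 ± 10.3 and 26.5 ± 3.16 FPKM (limma, adjusted p = 0.0757). Nuclear copies of these genes can share reads with them, which leaves single values uncertain. Among RNAs that report on RNA selection, also named after their values were seen, the nuclear noncoding RNAs MALAT1 and NEAT1 rose by 0.68 ± 0.13 and 1.02 ± 0.11 on the log2 scale and RN7SL1 fell by 0.22, while of 12 histone genes 2 rose and 2 fell (4 and 3 adjusted over the list alone). Neither of those lists passed (camera, adjusted p = 0.362 and 0.363). Nuclear genes of oxidative phosphorylation did not move with the mitochondrial mRNAs: 2 of 31 rose and 4 fell (1 and 1 adjusted over the list alone; camera, adjusted p = 0.832).

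The largest rises reported here fell outside these groups, apart from MT-ND6 and MT-ND5. SLC43A2, a transporter of large neutral amino acids, rose from 8.67 ± 0.827 to 50.3 ± 1.21 FPKM (log2 fold change 2.41 ± 0.08; limma, adjusted p = 7.67e-06). ABCG1, a cholesterol efflux transporter, rose from 1.32 ± 0.314 to 11 ± 0.0147 FPKM (log2 fold change 2.37 ± 0.11). The stress-induced cytokine gene GDF15 rose from 1.19 ± 0.570 to 9.74 ± 0.0389 FPKM (log2 fold change 2.32 ± 0.17), with as few as 25 reads in a vehicle library.

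Smaller rises ran through 4 further lists. Hypoxia and glycolysis genes had 21 of 33 members higher (22 higher and 1 lower adjusted over the list alone), with a median of 0.27 (camera, adjusted p = 3.88e-06; adjusted p = 0.37 with an estimated correlation). The largest changes were those of the carbonic anhydrase gene CA12, from 8.29 ± 0.626 to 19 ± 0.490 FPKM, the glucose transporter gene SLC2A3, from 7.23 ± 0.126 to 16.4 ± 0.0998 FPKM, and NDRG1, from 266 ± 14.8 to 487 ± 10.5 FPKM. Targets of NRF2, the oxidative stress regulator, had 14 of 24 members higher and 2 lower (16 and 2 adjusted over the list alone; camera, adjusted p = 0.000372; adjusted p = 0.325 with an estimated correlation). The aldo-keto reductase genes AKR1C1, from 2.74 ± 0.114 to 9.28 ± 0.738 FPKM, AKR1C3, from 27.0 ± 1.5 to 68.3 ± 0.836 FPKM, and AKR1B10, from 0.875 ± 0.0342 to 3.15 ± 0.579 FPKM, led this list. Reads may be split between such close paralogs. TGF-β and SMAD pathway genes had 13 of 21 members higher and 3 lower (14 and 3 adjusted over the list alone; camera, adjusted p = 0.000427; adjusted p = 0.325 with an estimated correlation). LTBP1, which tethers latent TGF-β, rose from 6.91 ± 0.134 to 13.4 ± 0.192 FPKM, the co-receptor gene TGFBR3 from 5.91 ± 0.320 to 11.3 ± 0.00779 FPKM, and ID2 from 0.809 ± 0.318 to 2.20 ± 0.172 FPKM. The ID2 call was lost with no filter (limma, adjusted p = 0.0509, the highest over the alternatives). Lysosome and autophagy genes had 13 of 24 members higher and 1 lower (14 and 1 adjusted over the list alone; camera, adjusted p = 0.000427; adjusted p = 0.429 with an estimated correlation). The autophagy receptor gene SQSTM1 rose from 97.6 ± 3.33 to 241 ± 0.0472 FPKM, TFEB, a transcription factor for lysosomal genes, from 6.50 ± 0.00635 to 12.1 ± 0.5 FPKM, and WIPI1 from 6.15 ± 0.347 to 10.7 ± 1.76 FPKM. SQSTM1 overlaps MGAT4B and WIPI1 overlaps PRKAR1A on the opposite strand, at 85.1 and 81.3 FPKM, so both are uncertain.

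The remaining 8 lists past the test are described with members chosen after their values were seen. Immediate early and AP-1 genes had 15 of 27 members higher and 5 lower, the same adjusted over the list alone (camera, adjusted p = 0.00076). KLF2 rose by 1.63 ± 0.06 and the MAP kinase phosphatase gene DUSP4 by 0.98 ± 0.06 on the log2 scale, whereas FOSL1, an AP-1 subunit, fell by 1.38. Epithelial and luminal genes had 9 of 16 higher and 3 lower, likewise over the list alone (camera, adjusted p = 0.00492), with AGR2 up by 1.66 ± 0.16 and GATA3 down (log2 fold change -0.57 ± 0.11). Lipid oxidation and PPAR genes had 10 of 17 higher and 1 lower, likewise over the list alone (camera, adjusted p = 0.00492), among them PDK4, which restrains pyruvate oxidation (1.21 ± 0.08), and the lipid droplet gene PLIN2 (1.13 ± 0.07). Endoplasmic reticulum chaperones had 8 of 22 higher, the same adjusted over the list alone (camera, adjusted p = 0.00801), among them DNAJB9 (0.59 ± 0.07). Heat shock genes were the other group to fall, with 9 of 16 lower and 1 higher (10 and 1 adjusted over the list alone; camera, adjusted p = 0.0108). HSPA8, the constitutive chaperone, went from 692 ± 17.4 to 434 ± 1.07 FPKM and HSPB1 rose from 98.9 ± 20 to 166 ± 8.11 FPKM. Of 5 tested aryl hydrocarbon receptor genes 4 rose and 1 fell, also over the list alone (camera, adjusted p = 0.0142), with CYP1B1 from 101 ± 10.2 to 195 ± 0.719 FPKM and CYP1A1 from 1.62 ± 0.379 to 0.892 ± 0.135 FPKM. Interferon response genes had 16 of 40 higher and 6 lower, the same adjusted over the list alone (camera, adjusted p = 0.0142), including IRF7 up by 0.77 ± 0.07. That call was lost among genes of at least 5 FPKM (camera, adjusted p = 0.0537, the highest over the alternatives). Mesenchymal genes had 8 of 18 higher and 1 lower (9 and 1 adjusted over the list alone; camera, adjusted p = 0.019), with FN1 up by 0.76 ± 0.07 and the urokinase gene PLAU down from 68.1 ± 2.25 to 23.2 ± 2.43 FPKM. This call was lost without MGH-CP1 replicate 1 (camera, adjusted p = 0.0521, the highest over the alternatives). With an estimated correlation the adjusted p was 0.357 for the lipid oxidation and interferon lists and 0.37 for the other 6.

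**Figure D3:**
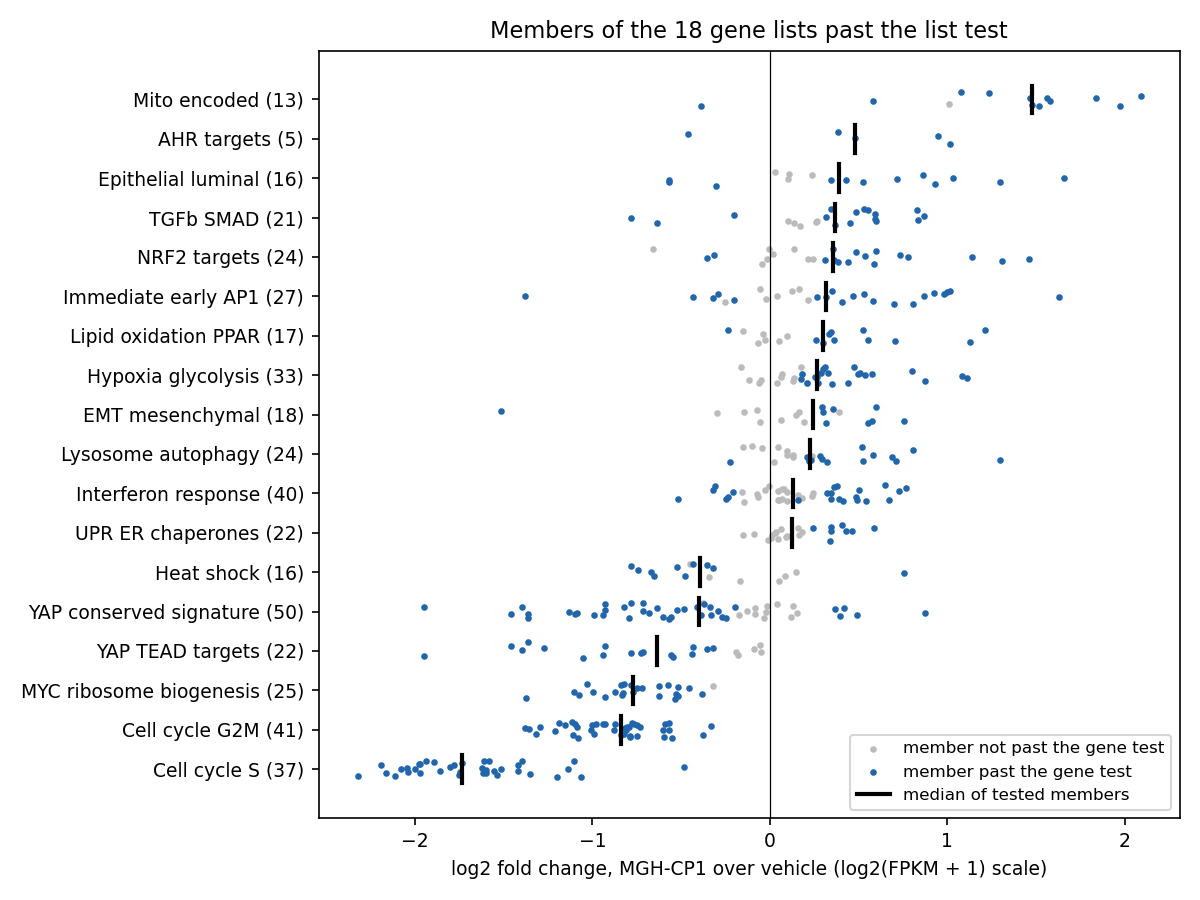
Log2 fold change of MGH-CP1 over vehicle (horizontal axis, log2(FPKM + 1) scale) for each tested member of the 18 lists past the camera test with a preset correlation, with the number of tested members in parentheses. Blue points passed the limma gene test, grey points did not, black bars mark list medians, and the S phase (-1.73) and mitochondrial (1.48) lists lie at the extremes.

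The list of PI3K and AKT genes, to which SOX4 had been added, held the most strongly raised of the genes named in every case. SOX4 (ENSG00000124766, chromosome 6, 21593972 to 21598847, plus strand), a transcription factor gene, rose from 5 ± 0.134 to 16.0 ± 2.21 FPKM (log2 fold change 1.5 ± 0.10; limma, adjusted p = 5.97e-05). ERBB3, a receptor that couples to PI3K, rose from 1.18 ± 0.0596 to 2.45 ± 0.224 FPKM, and FOXO1 from 1.51 ± 0.184 to 2.60 ± 0.0504 FPKM. The FOXO1 call was lost with no filter and without MGH-CP1 replicate 1 (limma, adjusted p = 0.0633 and 0.0553, the former the highest over the alternatives). Of the 28 tested members 12 rose and 4 fell (13 and 4 adjusted over the list alone), and the list did not pass (camera, adjusted p = 0.145). SOX4 and this list were chosen with knowledge of published work that may rest on these libraries and are not independent evidence.

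Among the lists that did not pass, the amino acid stress list of ATF4 targets came closest, with 5 of 29 members higher and 12 lower (5 and 15 adjusted over the list alone; camera, adjusted p = 0.0648). Fatty acid synthesis genes had 7 of 18 higher and 3 lower, actin and SRF genes 3 of 24 higher and 10 lower, and NF-κB and cytokine genes 8 of 26 higher and 8 lower (camera, adjusted p = 0.228, 0.434 and 0.459). Adjusted over the list alone these counts were 7 and 3, 4 and 10, and 9 and 8. Cholesterol synthesis genes had 5 of 26 higher and 5 lower (camera, adjusted p = 0.832), Wnt genes 5 of 12 higher and 5 lower, p53 targets 5 of 21 higher and 8 lower, metallothionein genes 2 of 6 higher and 1 lower, and Notch genes 1 of 7 lower (camera, adjusted p = 0.872 for each of these 4). Adjusted over the list alone they were 5 and 4, 6 and 5, 5 and 8, 2 and 2, and 1 lower. Basal keratinocyte genes had 2 of 9 higher and 2 lower, apoptosis genes 3 of 15 higher and 5 lower, and extracellular matrix genes 7 of 25 higher and 9 lower (camera, adjusted p = 0.946, 0.948 and 0.948), or 2 and 2, 4 and 5, and 7 and 10 adjusted over the list alone. The list median, mean and test differed in sign for the basal, cholesterol, fibroblast, metallothionein, Notch, oxidative phosphorylation, p53, palmitoylation and Wnt lists. Markers of other cell types stayed low: the highest endothelial marker averaged 0.600 FPKM, the highest immune marker 3.11 FPKM, and none of the 3 tested fibroblast markers passed (camera, adjusted p = 0.872). Among immune markers CSF1R, named after its values were seen, rose from 1.54 ± 0.255 to 3 ± 0.269 FPKM.

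In all, 18 of the 38 tested lists passed camera with the preset correlation, 12 upward and 6 downward. With an estimated correlation 0 of the 38 passed, the lowest adjusted p being 0.308, and 5 had an unadjusted p under 0.05. This form rests on 2 residual degrees of freedom, so few lists could pass it after adjustment. For YAP and TEAD targets the estimate was -0.004, below the preset 0.01, yet the camera p rose from 4.9e-09 to 0.023. Other lists had estimates above 0.01, the highest being 0.82 for ribosomal proteins, a list that did not pass. Among lists that passed with the preset value, the highest were 0.60 for mitochondrial mRNAs, 0.20 for lysosome and 0.19 for hypoxia genes. The estimate was 0.15 for ribosome biogenesis and 0.10 for S phase genes. It was below 0.01 for others, such as the NRF2, TGF-β and conserved YAP lists. If the high estimates hold, the preset form gives those lists too small a p. All estimates rest on 2 residual degrees of freedom. Failure in the estimated form therefore does not decide whether the members of a list vary together. By fry, 22 lists moved on balance in 1 direction and 36 passed its mixed form. Fry compares members with no change, not with the other genes, and 5311 of the 11790 genes were called. Even the palmitoylation list passed the mixed form (fry, adjusted p = 0.00114), so these counts do not bear on the camera results.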

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

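The alternatives added after seeing the data were voom on recovered reads, scaling to nuclear reads, and the GC and length correction. Higher genes numbered 2355 in the reported fit and 1568 with no filter, where 24640 genes shared the adjustment, and 1460 to 2556 when 1 library was left out (a lone library was assumed to vary like the other group), the fewest without MGH-CP1 replicate 1 (1524) or 2 (1460), the cause not being tested. Lower genes numbered 2956, and 2033 to 3153 over the 16 alternatives. Lists past the test numbered 18, and 18 to 20 over the alternatives; the TEAD target median ranged from -0.72 to -0.57. Over 747 values of the 48 named genes under alternatives, 737 kept the side of the threshold. Another 8 fell short of it (TEAD2 5 times, once under the block, FOXO1 2 and ID2 1). The other 2 newly passed (YAP1 at 0.15 after the GC and length correction, TEAD1 without vehicle replicate 1). Direction was compared only where the reported fit or the alternative passed, and 0 of those values reversed. TEAD1 and TEAD3, which did not pass in the reported fit, ranged across 0 (-0.20 to 0.05 and -0.09 to 0.03). Over 606 values of the 38 lists, 595 kept the side of the threshold and 2 fell short (mesenchymal, interferon). Another 9 newly passed (ATF4 4 times, Hippo and ribosomal proteins 2 each, histones 1), and by the same comparison 0 reversed. Quantile normalization (2803 higher) and the GC and length correction (3056 higher, the most) each turned the balance, with 52.0% of calls higher against 44.3%, and the median of all genes moved by under 0.1 throughout. Replicate numbers did not pair the samples (r = 0.050 across genes between the replicate differences of the groups, 2 pairs); with the number as a block, 2453 genes were higher and 3036 lower. Tests planned for a table of counts were not run, since the values were FPKM. Depth limits short genes near 1 FPKM most, such as AKR1B10 and ID2, with as few as 24 and 20 reads in a library.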

Other observations

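Of the tests given here, the gene lists behind the hypotheses on LXR, FOXO, homologous recombination and mitochondrial transcription, the lists for mitochondrial ribosomes, tRNA synthetases and prostaglandins, the GC and length correction and the scaling to nuclear reads were chosen only after the gene results had been seen; each test's bounds were written before its own result. For the tests against random lists, the value printed was changed from the percentile to the list median after these results were seen. The members named here from the later lists, and KLHL24, BMF, PTGS2 and PTGES, were also chosen after their values were seen. Beside ABCG1, the cholesterol efflux gene ABCA1 went from 14.6 ± 1.55 to 36.0 ± 0.735 FPKM, and the lipid synthesis genes SREBF1 from 30.4 ± 1.63 to 73.1 ± 0.525 FPKM and SCD from 38.7 ± 0.00224 to 100 ± 4.72 FPKM (all chosen after their values were seen). These are known targets of the liver X receptors (LXR), and a hypothesis that LXR targets rose as a set was tested on members other than these 4. Of 8 such genes 7 rose, including MYLIP (log2 fold change 0.77 ± 0.07) and NR1H3 (0.60 ± 0.09), and their median of 0.45 lay above the 95% range of 10000 random lists matched on mean expression (-0.31 to 0.26). The LXR list did not pass camera with an estimated correlation (adjusted p = 0.199). The rise of KLHL24 (1.28 ± 0.09) and BMF (1.51 ± 0.11) prompted the same test for FOXO targets: 13 of 17 other tested members rose, among them SOD2 (1.21 ± 0.05) and TRIB1 (0.90 ± 0.08), with a median of 0.38 against a range of -0.23 to 0.17. The FOXO list did not pass camera with an estimated correlation either (adjusted p = 0.164). INSR, RICTOR, ERBB3 and IRS2 also belong to the PI3K list tested before. Without them 10 of 13 members rose, with a median of 0.38 against a range of -0.27 to 0.19, in a test added later. Each set may have risen as such, while what drives them was not tested.

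Homologous recombination and Fanconi anaemia genes fell broadly. Of 27 members whose values had not prompted the list, 24 were lower, among them BRCA1, from 9.27 ± 0.878 to 2.70 ± 0.0781 FPKM, and FANCA, from 7.38 ± 0.627 to 2.5 ± 0.254 FPKM. Their median of -0.94 lay below the range of matched random lists (-0.18 to 0.14), in line with a fall of the set, although many of these genes are also cell cycle regulated and these readings cannot be separated with these lists. The list did not pass camera with an estimated correlation (adjusted p = 0.164). Nuclear genes of the mitochondrial ribosome had 24 of 37 members lower (median -0.32), and cytosolic tRNA synthetases 11 of 20 lower and 1 higher (median -0.33), with FARSB at -1.14 ± 0.08. PTGS2 and PTGES, enzymes of prostaglandin E2 synthesis, rose from 1.12 ± 0.289 to 6.92 ± 0.480 FPKM and from 24.6 ± 1.48 to 82.6 ± 1.30 FPKM, while the 6 other tested prostaglandin genes had 1 higher and 4 lower, and that list did not pass (camera, adjusted p = 0.324). Adjusted over the 7 later lists, camera gave p from 1.67e-09 to 0.00126 for the other 6 lists, and from 0.164 to 0.199 with an estimated correlation. As for the fixed lists, the estimated form rests on few residual degrees of freedom, so failure to pass it decides little.

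The fall of TEAD targets was weighed against a general fall of genes at their level of expression and against library scaling. The list median of -0.63 lay below the range of 10000 matched random lists (-0.20 to 0.14), which argues against a general fall at that level. Under median-ratio scaling it was -0.61. That scaling moved the median of all genes only from -0.02 to 0.004, so it could not have moved the list far. It shows only that the list fell relative to the median tested gene. Without cell cycle members the median of the conserved YAP signature was -0.34, with 26 of 43 genes lower and 5 higher, and without the 9 TEAD targets as well it was -0.22, with 17 of 34 lower and 5 higher, so cell cycle members did not carry all of its fall. A biological hypothesis is that MGH-CP1 lowered TEAD-dependent transcription. Whether the fall followed from lost palmitoylation, from the lower TEAD4 mRNA or from slower growth was not tested, and replicate libraries of unknown origin leave culture differences open.

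The fall of S phase genes kept its size when libraries were processed differently. After the correction for GC content and gene length the list median was -1.65, which argues against that bias as the whole cause. Under median-ratio scaling it was -1.71. That scaling moved the median of all genes only from -0.02 to 0.004, so it shows only a fall relative to the median tested gene. A candidate explanation is that fewer treated cells were in S phase, and lower transcription per cycling cell could give the same values. No cell count or phase measurement was used here, so these remain open.

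The rise of mitochondrially encoded mRNAs was weighed against reads shared with nuclear copies. Reads summed over these genes and the copies were 2.27-fold higher in the lowest MGH-CP1 library than in the highest vehicle library. Only 16 of 175 listed copies had reads. Scaled to library size, they held 112 against 18086 on these genes in MGH-CP1 replicate 1. The sum therefore nearly repeats the rise of these genes, and argues only against a shift of reads counted on the copies. Copy reads counted on these genes would raise the sum alike, so it cannot decide on shared reads. Scaled to nuclear reads the list median was 1.49, but these genes hold so few reads that this scaling could move it by only 0.02, so that test is uninformative; under median-ratio scaling and quantile normalization the median was 1.5 and 1.13. Sense-intronic transcripts, taken as a sign of weaker poly(A) selection, had a median of 0.0836 (37 genes, 95% bootstrap interval -0.08 to 0.22). This met the bound set against that explanation, but the explanation was reopened after the result was seen. The bound assumed that these transcripts lack poly(A) tails, and MALAT1 and NEAT1 rose (0.68 and 1.02). RN7SL1, by contrast, fell by 0.22 on the log2 scale. The histone list did not pass (median 0.15, 2 of 12 higher and 2 lower, camera, adjusted p = 0.363). It holds replication histones, and S phase genes fell (median -1.73), so it cannot tell for or against weaker selection. Nuclear factors of mitochondrial transcription did not rise with the mRNAs, since 15 of 22 fell, TFAM among them (-0.80 ± 0.10), with a list median of -0.32 against a random range of -0.19 to 0.15. Slower turnover, more mitochondrial genomes per cell and less nuclear mRNA per cell stay open as untested. Poly(A) selection and reads shared with nuclear copies also stay open.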
